A study of soil metagenome with 39 samples.

How the data were processed

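The series holds soil metatranscriptomes, that is, sequenced RNA of the whole soil community, from trays of soil that were burned in a prescribed fire or left unburned. Per the labels' protocols, 3 trays per gap were burned, soil was taken from the top 5 cm within 4 hours of the fire and frozen in liquid nitrogen, and total RNA was extracted, depleted of ribosomal RNA and sequenced on an Illumina NovaSeq. Reads were trimmed with Trimmomatic 0.36, per the submitters' processing notes. Reads were merged and depleted of ribosomal sequences before annotation, per the file headers, and the aligner and the versions of the annotation databases are not given in the sources used here.

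Both tables hold normalised signal values that the authors deposited, not counts. In each sample the values are whole multiples of a fixed step within a tolerance of 0.05 for 100% of KO values and for 99.8% to 100% of genus values, so that the deposited signal is a read number divided by a factor per sample, and the factor is 1 for a single control sample. How the authors set that factor is not given in the sources used here. In the genus table no value lies between 0 and about 73.2 to 77.3, so a 0 there stands for any value below that level, whereas in the KO table a single read is visible. Cells at 0 made up 47.0% of KO values and 51.5% of genus values. Recovered reads per sample served to describe depth and for limma voom as an added alternative, and their precision is limited by counting error in the smallest KO libraries, of which the lowest has 814 reads. All sample columns in the tables were used.

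Treatment was taken from the labels. Of 39 labelled samples, 18 fire and 21 control, 37 had values, with 2 labelled fire samples (gaps 28 and 89) not analysed here. The labels do not say which burn block a tray stood in, so no within-block value can be given, and separate soil trays were taken as replicates. Nothing in the labels says that samples are separate beyond their trays and gaps. No pair of libraries agreed within sampling noise (666 pairs, lowest chi-square per degree of freedom 1.88).

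The main test was limma 3.58.1 with trend (R 4.3.3) on log2(value + pseudocount) with Benjamini-Hochberg adjustment over all rows of a table. The pseudocount was 0.0414 for KOs, the smallest value above 0, and 1 for genera, whose sample totals exceed 10000. Log2 differences are on that scale. They understate changes of rows whose values lie near the pseudocount, and overstate those of genera with zeros, since a 0 in that table stands for any value below the floor and the pseudocount lies far under it. Differences of KOs with zeros can be overstated too. A single read was worth a median of 0.249 normalised units and up to 1, above the KO pseudocount, so a step from 0 to 1 read counts for more in shallow samples. No filter on low values was applied. In the KO fits limma took the variance of each KO wholly from the trend over KOs. The fire fit had 44625 degrees of freedom for KOs, against 42.3 for genera. The SE and p values of single KOs therefore rest on the spread of KOs of like level, not on each KO's own spread. Fire against control was fitted without covariates; time since last fire, number of past fires and their interactions with fire were fitted as slopes per SD with treatment in the model. Designs, lists and the rule for named genes were fixed before the data were examined. Had the tables held counts, a count test was planned; since they hold normalised values, the log-scale test was used.

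Lists of KOs and genera were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a table and term. Of the lists fixed, 24 KO lists and 9 genus lists with at least 3 measured members were tested. The lists for cold shock, sporulation, nitrogen fixation, mobile elements, carbon fixation enzymes, Acidobacteria, nitrifier genera, Chloroflexi with Deinococcus-Thermus and Myxobacteria had fewer members and were not tested. The rule for named features took up to 10 rising and 10 falling KOs (8 and 8 genera) with adjusted p under 0.05 and a mean above the table's lower quartile in the fire contrast, up to 4 members of each list with the smallest p, and for the other terms the 5 of each direction with the smallest p past the threshold, or the 3 with the smallest p where fewer than 3 passed. KO members named outside it were chosen after their values were seen. They were GroEL, HtpG and beta-tubulin with fire, ClpX or ClpP or both, catalase, the photosynthesis proteins D1 and D2, and the collagen KOs.

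Whole profiles were compared by PERMANOVA (vegan 2.7.1, adonis2, marginal terms, Bray-Curtis distance), and sums, ratios and diversity by two-sided permutation tests, with exact sign-flip tests over the 9 gaps that had both treatments. Correlations over samples were given with permutation p values and adjusted over 23 relations. Figures were drawn with matplotlib 3.10.9.

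The gap label pairs samples, since a control and a fire tray of a gap came from the same site. Deviations from group means correlated within a gap with a median of 0.0009 for KOs (range −0.0321 to 0.108, with 1 of 9 gaps matching itself best) and 0.146 for genera (−0.0441 to 0.256, 5 of 9), against −0.0083 and −0.0178 between gaps. Fits with the gap as a fixed or a random block were alternatives. Other alternatives were other pseudocounts, a filter on low values, other scalings, limma without trend or with array weights, rank tests, covariates, log-scaled fire history, control samples alone and leaving out each sample. Chosen after the data had been seen were voom on recovered reads, leaving out libraries under 1000 KO reads, a scaling without collagen KOs, list tests for the number of past fires, the sums over groups of genera, and the ratios between KOs.

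The fire test was run on simulated data with 200 changed features. For KOs changed by fire, limma recovered 2.5% of 80 simulated 2-fold changes, 32.8% of 58 4-fold changes and 75.8% of 62 8-fold changes, with 3 false calls among 1075 unchanged KOs. For genera changed by fire it recovered 29.4% of 68, 57.1% of 49 and 63.9% of 83, with 2 false calls among 315 unchanged rows. Most 2-fold KO changes were therefore missed in the simulated data. Whether depth, the spread between samples or their number limits the recovery was not separated. These figures hold for the simulated data and may not carry over to the real KOs, which varied together within lists. The estimated correlation was 0.67 for chaperones and 0.38 for ribosomal proteins. Other splits of the real samples called at most 1 KO, but up to 16 where the splits part as many gaps. False calls in the real data may therefore exceed the simulated ones.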

Results

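The series measured which genes were being transcribed in soil shortly after a prescribed fire, in places whose earlier fire history differed. Soil came from open sand gaps, the bare patches between shrubs of a rosemary scrub. Trays of soil from each gap were burned or kept outside the burned area, and the top 5 cm was frozen within 4 hours of the fire. Total soil RNA, depleted of ribosomal RNA, was sequenced, so that the reads come from bacteria, archaea, fungi, protists, animals and plants together. Values were read for 21 control samples and 16 fire samples from 28 gaps, and 2 further samples labelled as fire were not analysed here. In 9 gaps both a control and a fire sample had values. Time since the last earlier fire ran from 1 to 33 with a median of 10, taken here as years, and the number of past fires from 1 to 7 with a median of 3. The values came as a table of 1275 KOs, which are KEGG Orthology groups of genes that share a function across organisms, and a table of 515 rows at the level of genus. Recovered KO reads per sample had a median of 5437 and reached 42136, and recovered genus reads ran from 372493 to 9507690. The KO total was 0.105% to 1.19% of the genus total of the same sample, so gene-level values rest on far fewer reads than genus-level values.

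The first comparison asked which genes changed with fire. Transcripts of some heat shock chaperones and quality-control proteases had higher means in fire soil, and transcripts of proteins typical of eukaryotic cells had lower means. The mean over all 8 chaperones was not higher past the threshold (0.72 ± 0.63 on the log2 scale, SE, permutation p = 0.257). Both lists lost their calls with the estimated correlation (adjusted p 0.905 and 0.788). ClpX (K03544), ClpP (K01358), HtpG (K04079) and BiP (K09490) had lower mean normalised values in fire. On the log2 scale only 1 of the 8 chaperones and 1 of the 6 proteases was lower, so the direction of some members depended on the scale. DnaK (K04043), the Hsp70 chaperone of bacteria, averaged 93.8 ± 145.7 normalised units (SD, n = 16) in fire soil and 11.6 ± 9.77 (SD, n = 21) in control soil, and 7 of the 16 fire samples lay above the highest control value of 34.97. ClpB (K03695), which pulls proteins out of aggregates, averaged 31.7 ± 48.6 in fire soil and 4.16 ± 3.27 in control soil, again with 7 fire samples above the highest control. Actin (K05692), a cytoskeletal protein of eukaryotes, averaged 8.95 ± 6.44 in fire soil against 35.4 ± 35.7 in control soil. The 8 measured members of the chaperone list together made up 11.1 ± 10.03% of the KO total in fire soil and 3.92 ± 2.26% in control soil. The 9 eukaryotic markers made up 0.834 ± 0.776% and 2.70 ± 2.89%.

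**Figure D1:**
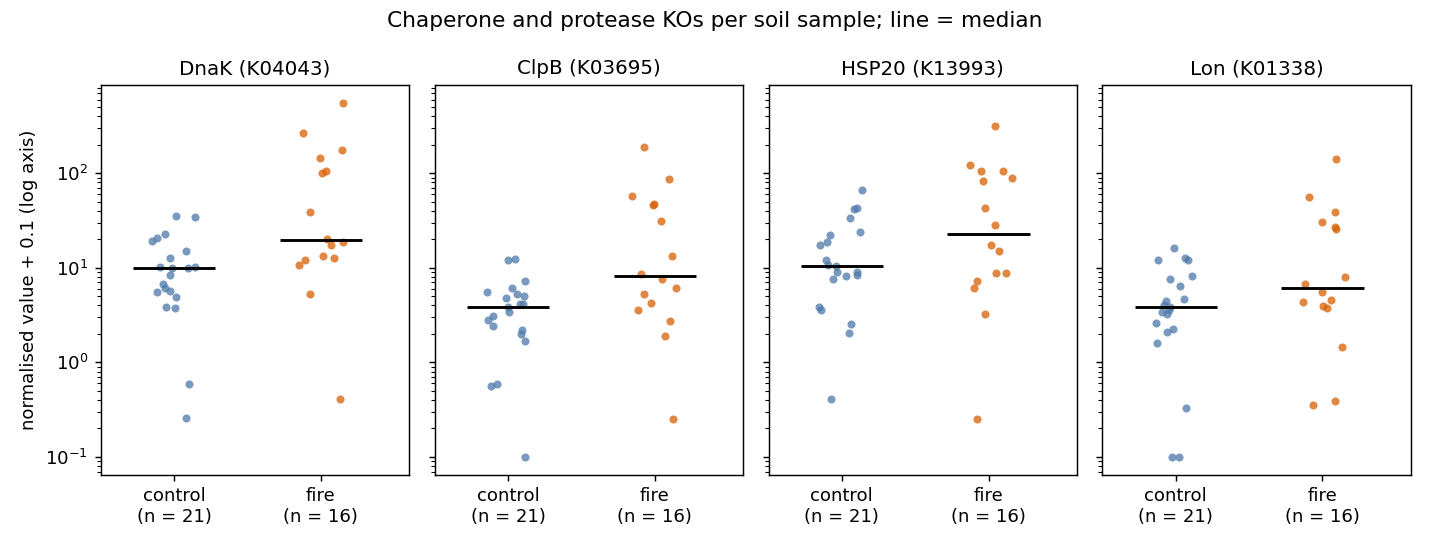
Normalised values of DnaK, ClpB, HSP20 and Lon in each soil sample, on a log axis after adding 0.1, with control samples in blue (n = 21) and fire samples in orange (n = 16) and a black line at the group median. For DnaK the control samples end at 34.97 while 7 fire samples lie above that value, and the medians were 9.81 in control and 19.4 in fire soil.

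None of the 1275 KOs passed an adjusted p of 0.05 in limma over all KOs. The smallest adjusted p was 0.341, and 79 KOs had an unadjusted p under 0.05 (30 higher and 49 lower in fire), where 63.75 would be expected by chance. The balance of directions depended on the scaling, with 60 higher and 55 lower under the centred log-ratio, 24 and 77 with the same total without collagen KOs, and 16 and 1.2e+02 with voom on own totals. The centred log-ratio called 8 KOs, 7 of them higher, and limma voom on recovered reads scaled to each sample's own KO total called 7, of which 2 were higher; DnaK and ClpB were called by both. Array weights called DnaK alone (adjusted p = 0.0320), as did leaving out the fire sample of gap 94 (adjusted p = 0.00412). The fits with the gap as a block, the rank test and voom with the authors' factor each called 0 KOs.

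Among the 8 members of the list of heat shock proteins and chaperones, 7 were higher in fire on the log2(value + pseudocount) scale, with a median difference of 0.72. Adjusted over the list alone, 3 members passed. These list p values rest on variance shared by KOs of like level, not on each member's own spread. DnaK rose by 2.03 ± 0.56 on the log2 scale (SE, limma adjusted p over the list 0.0022, adjusted p over all KOs 0.341) and was higher in 6 of 9 gaps with both treatments, and ClpB rose by 1.96 ± 0.63 (0.00753 and 0.341). BiP (K09490), the Hsp70 of the eukaryotic endoplasmic reticulum, fell by 1.64 and was higher in fire in 0 of the 9 gaps. HSP20 proteins (K13993), small chaperones that hold unfolding proteins, averaged 60.02 ± 81.3 in fire and 16.8 ± 16.7 in control soil, a difference of 1.12 with a list p of 0.0875. Their medians were 22.7 and 10.3, and the highest fire value was 318.9, in gap 19E. HSP20 was lower in the fire sample of gaps 9, 40, 43, 90 and 94. GroEL (K04077), the barrel-shaped chaperonin, differed by 0.33 ± 0.54. The list passed camera with preset correlation (adjusted p = 0.00155), and its call was lost with the estimated correlation (adjusted p = 0.905), with fry (0.987) and with the gap as a fixed block (0.790).

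Of 6 proteases of protein quality control, 5 were higher (median 1.00, camera adjusted p = 0.00155, adjusted p = 0.788 with the estimated correlation and 0.623 with the gap as a fixed block). In this list ClpB alone passed adjusted over the list alone (list p = 0.0114). ClpB is the chaperone described above and is counted in both lists, so no other member of the protease list passed. The 2 list calls are therefore not separate. Lon (K01338), which degrades misfolded proteins, averaged 22.2 ± 35.5 in fire (14.35 ± 16.89 without the sample of gap 19E) against 5.22 ± 4.55 in control soil, and the serine protease PepD (K08372) averaged 1.24 ± 1.17 against 0.405 ± 0.422 and was higher in 7 of 9 gaps. The oxidative stress list had 6 of 9 members higher (median 0.41, camera adjusted p = 0.0274, adjusted p = 0.991 with the estimated correlation and 0.790 with the gap as a fixed block), with 0 members passing limma adjusted over the list alone and 1 at an unadjusted p under 0.05. That member was thioredoxin (K03671), a protein that reduces disulfide bonds, with 4.99 ± 6.49 in fire and 1.41 ± 1.33 in control soil. Thioredoxin reductase (K00384) averaged 6.63 ± 9.77 and 2.01 ± 1.602, and catalase (K03781) 4.21 ± 4.32 and 5.09 ± 5.21. The oxidative list was not called without the fire sample of gap 19E (0.0639), 40 (0.0734) or 93 (0.0620) or the control sample of gap 99 (0.0762). For these KO lists fry gave no call.

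All 9 eukaryotic markers were lower in fire soil, and 6 fell when adjusted over the list alone. These were alpha-tubulin (K07374, −2.005 ± 0.68), EF-1-alpha (K03231, −1.58 ± 0.71), beta-tubulin (K07375, −1.46 ± 0.64), actin (−1.43 ± 0.56), histone H3 (K11253, −1.42 ± 0.63) and histone H2B (K11252), which was listed at 0 in every fire sample and averaged 0.216 ± 0.392 in control soil. The list median was −1.42. The list had the smallest p of the 24 KO lists (camera adjusted p = 1.1e-07, adjusted p = 0.273 with the estimated correlation), and with the gap as a fixed block its adjusted p was 0.00497. The collagen KOs K06236 and K19720, named for structural proteins of animals, took 40.3 ± 18.6% of the KO total in control soil and 31.4 ± 20.2% in fire soil (permutation p = 0.0792 for the log2 share). Animals took only 4.55% and 4.35% of the genus total, and whether these are reads of low complexity wrongly assigned to collagen was not tested.

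**Figure D2:**
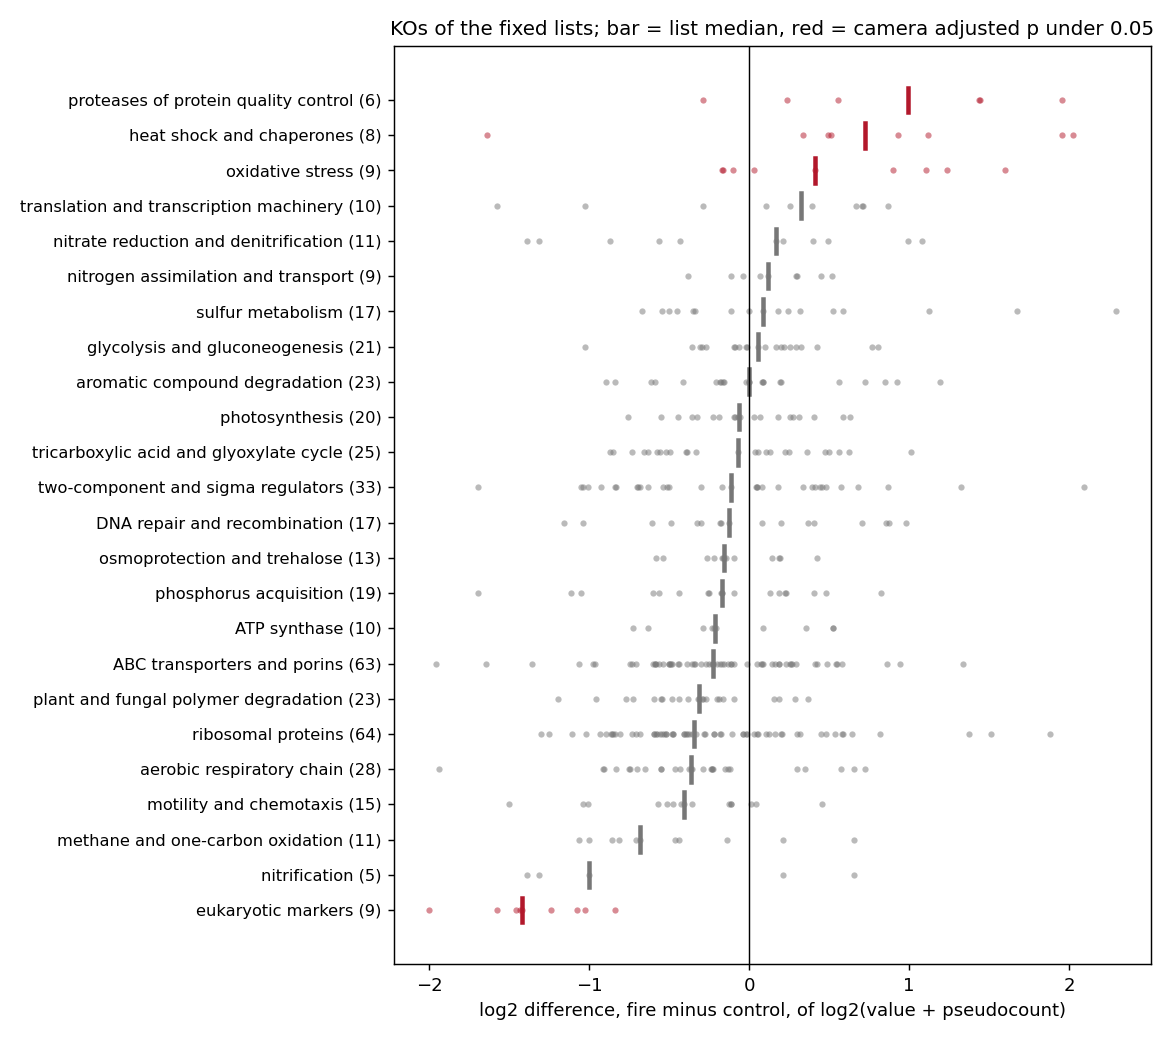
Differences between fire and control soil, on the log2(value + pseudocount) scale, for the members of the 24 fixed KO lists, with the number of measured members in brackets, a dot per KO and a bar at each list's median. Red lists passed camera with preset correlation, with medians of −1.42 for eukaryotic markers, 0.41 for oxidative stress, 0.72 for chaperones and 1.00 for quality-control proteases.

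The other 20 KO lists did not pass. In sulfur metabolism 10 of 17 members were higher, and 2 rose when adjusted over the list alone. They were the CysO-dependent cysteine synthase (K21148, 2.29 ± 0.70, list p = 0.0175) and thiosulfate sulfurtransferase (K02439, 1.67 ± 0.59, list p = 0.0364), with a camera adjusted p of 0.199 for the list. In nitrate reduction and denitrification 6 of 11 were higher (0.880), and in nitrification 2 of 5 (0.388). The nitrate reductase subunits NarG (K00370, −1.39 ± 0.71) and NarH (K00371, −1.32 ± 0.66), counted in both lists, had list p values of 0.180 and 0.122. In nitrogen assimilation and transport 6 of 9 were higher (0.423). Genes of carbon use showed no list call. In plant and fungal polymer degradation 19 of 23 were lower (0.292), among them cellobiohydrolase (K19668, −1.20 ± 0.54, list p = 0.600), and in aromatic compound degradation 10 of 23 were higher (0.423), with catechol 2,3-dioxygenase (K00446) at 1.19 ± 0.61. Of methane and one-carbon oxidation KOs 9 of 11 were lower (0.284), including the lanthanide-dependent methanol dehydrogenase (K23995, −1.07 ± 0.58).

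In energy metabolism 23 of 28 respiratory chain KOs were lower (camera adjusted p = 0.284), with the mitochondrial cytochrome c oxidase subunit 1 (K02256) at −1.94 ± 0.62 and a list p of 0.0510. Higher members numbered 4 of 10 for ATP synthase (0.973), 12 of 25 for the tricarboxylic acid cycle (0.973), 11 of 21 for glycolysis (0.423) and 9 of 20 for photosynthesis (0.469). For growth machinery they numbered 20 of 64 ribosomal proteins (0.423) and 7 of 10 translation and transcription KOs (0.423), with EF-Tu (K02358), which brings tRNA to the ribosome, at 84.5 ± 110 in fire and 36.99 ± 15.3 in control soil (0.71 ± 0.47). Motility and chemotaxis had 12 of 15 lower (0.284), with pilin Flp (K02651) at −1.50 ± 0.59. Transporters and porins had 41 of 63 lower (0.641), phosphorus acquisition 12 of 19 (0.710) with the phosphate regulator PhoB (K07657) at −1.70 ± 0.61, DNA repair 9 of 17 (0.641), osmoprotection and trehalose 9 of 13 (0.973), and regulators 17 of 33 (0.973). Among the regulators the sigma factor K03087 stood at 2.10 ± 0.71 with a list p of 0.0873, and it was higher in 7 of 9 gaps.

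At the level of genus, fire lowered 6 rows and raised 1. Virgibacillus, named for a spore-forming bacterium, averaged 48.1 ± 70.4 in fire soil and 854 ± 1096.3 in control soil, a log2 difference of −5.95 ± 0.95 (limma adjusted p = 7.5e-05), and it was lower in 8 of the 9 gaps with both treatments. The parasitic flagellate Trypanosoma fell by 2.77 ± 0.59 (adjusted p = 0.00654), from 2519.3 ± 2567.4 to 420 ± 393, and was lower in 8 of 9 gaps. Its relative Phytomonas, whose known members live in plants and insects, fell by 3.04 ± 0.80 (adjusted p = 0.0357). Geosiphon, a soil fungus that houses cyanobacteria, fell by 1.39 ± 0.33 (adjusted p = 0.0123), from 4191 ± 3564.1 to 1434 ± 741. Methanosarcina, a methane-producing archaeon, rose by 4.095 ± 1.06 (adjusted p = 0.0327) and was above 0 in 14 of 16 fire samples and 7 of 21 control samples. Within gaps, Methanosarcina was higher in fire in gaps 13, 24N, 31, 43 and 59. It was lower in gaps 9, 90 and 94 and listed at 0 in both samples of gap 40. Phytomonas was higher in fire in gaps 43, 90 and 94, and Geosiphon in gaps 59, 90 and 94. Both were lower in the other gaps with both treatments.

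The remaining pair carried animal names. Gigantopelta, a deep-sea snail, fell by 4.22 ± 0.94 (adjusted p = 0.00654), and Labeo, a freshwater fish, was listed at 0 in all 16 fire samples and above 0 in 13 of 21 control samples (adjusted p = 0.00654). A value of 0 in this table means below about 73.2 to 77.3 normalised units, the smallest values above 0 in the samples, and log2 differences of rows with many zeros are overstated by the pseudocount of 1. With a pseudocount of 50% of the smallest value above 0, the same rows were called with smaller differences, −2.95 for Virgibacillus, −2.32 for Trypanosoma, −1.71 for Phytomonas, −1.35 for Gigantopelta and 1.43 for Methanosarcina. In all, 73 of 515 rows had an unadjusted p under 0.05. With the gap as a fixed block, so that the 9 gaps with both treatments carried the fire contrast, limma called 0 genera (39 at an unadjusted p under 0.05, adjusted p = 0.485 for Virgibacillus), and with the gap as a random block it called 10, all 7 among them. Array weights left only Virgibacillus, and voom on recovered reads called 55 rows, 6 of the 7 among them.

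**Figure D3:**
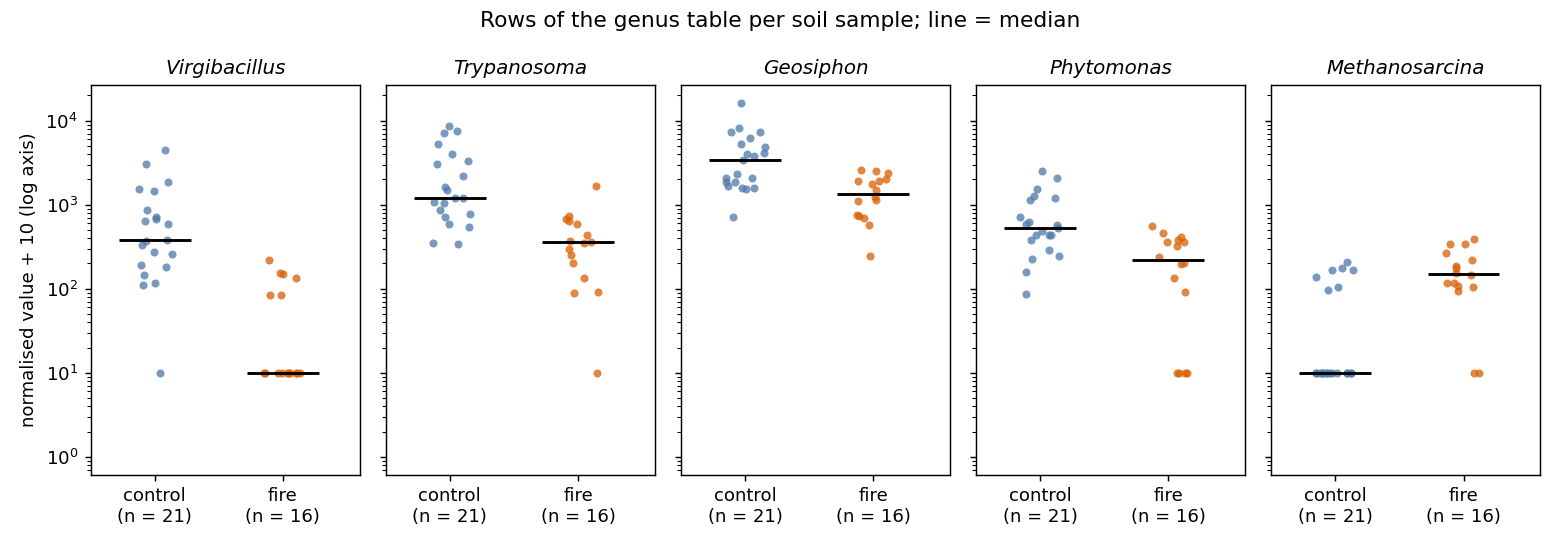
Normalised values of Virgibacillus, Trypanosoma, Geosiphon, Phytomonas and Methanosarcina in each soil sample, on a log axis after adding 10, with control samples in blue (n = 21), fire samples in orange (n = 16) and a black line at the median. Virgibacillus was above 0 in 20 control and 6 fire samples, and Methanosarcina in 7 control and 14 fire samples.

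Among the 9 genus lists, 2 passed camera for fire. Camera compares a list with the other rows of the table, in which 253 of 515 rows were eukaryotic. All bacteria summed were themselves higher in fire by 0.34 on the log2 scale (permutation p = 0.00151). Whether the 2 lists rose more than other bacteria was not tested. Of 12 Actinobacteria 10 were higher in fire soil (median 0.41, camera adjusted p = 0.0382, adjusted p = 0.615 with the estimated correlation, fry adjusted p = 0.112), and 3 rose when adjusted over the list alone. Streptomyces, a filamentous antibiotic producer, averaged 69470 ± 16323 in fire and 51224 ± 15409 in control soil (0.47 ± 0.13, list p = 0.0144, adjusted p over all rows 0.0617), Nocardia differed by 0.69 ± 0.26 and Rhodococcus by 0.48 ± 0.18. Of 14 genera that are host-associated or often found in reagents 13 were higher (median 0.47, camera adjusted p = 0.0285, adjusted p = 0.0860 with the estimated correlation, fry adjusted p = 0.000125), led by Streptococcus (0.51 ± 0.20), Cutibacterium (0.67 ± 0.28) and Haemophilus (0.64 ± 0.28), with 0 passing limma adjusted over the list alone and 3 at an unadjusted p under 0.05. With the gap as a fixed block the adjusted p was 0.102 for Actinobacteria and 0.0434 for the host-associated genera. With the same total in every sample neither list passed (0.0938 and 0.0555). The host-associated list also missed with genera above 0 in at least 50% of samples alone (0.0753), and Actinobacteria with the centred log-ratio (0.0507), with fire history as covariates (0.0538) and without the control sample of gap 20, 24N or 89 or the fire sample of gap 31, 43, 70N or 93 (adjusted p 0.0536 to 0.0798).

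Spore-forming Firmicutes had 4 of 7 genera higher (camera adjusted p = 0.578, direction down with a median of 0.05, since Virgibacillus fell), with Geobacillus, a heat-loving spore former, at 0.73 ± 0.32 and higher in 8 of 9 gaps. The genera often reported after fire had 4 of 6 higher (0.578), of which Streptomyces rose adjusted over the list alone (0.00718), while Arthrobacter averaged 3057 ± 2169 in fire and 1934 ± 799.45 in control soil. Cyanobacteria (4 of 5 higher, 0.578), Bacteroidetes (4 of 6, 0.578), Planctomycetes and Verrucomicrobia (2 of 3, 0.720), Rhizobiales (3 of 6, 0.796) and Burkholderiales (2 of 4, 0.796) did not pass, with 0 members passing limma adjusted over each of these lists alone. The cyanobacterium Microcystis averaged 1954 ± 3608 in fire (1112.7 ± 1345.5 without the sample of gap 40) and 782 ± 1017.2 in control soil (adjusted p = 0.417) and was higher in 8 of 9 gaps.

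Fire accounted for 7.61% of the variation in genus profiles (PERMANOVA, permutation p = 0.0027) and 6.79% of that in KO profiles (permutation p = 0.0235). With permutations within the 9 gaps that had both treatments the shares were 6.90% (permutation p = 0.184) and 4.70% (permutation p = 0.508), and on square roots the KO share was 3.26% (permutation p = 0.221). Bray-Curtis distance gives most weight to the largest rows, and the collagen KOs took 40.28% of the KO total in control and 31.35% in fire soil. The KO share was not computed without them. Dispersion within groups did not differ past the threshold (permutation p = 0.123 for genera and 0.345 for KOs). Shannon diversity of genera was 3.88 ± 0.18 in fire soil (SD, n = 16) and 3.94 ± 0.20 in control soil (n = 21, permutation p = 0.349). Shannon diversity of KOs was 3.92 ± 1.19 and 3.88 ± 1.24 (permutation p = 0.939), and leaving out the collagen KOs turned the difference to −0.460 (permutation p = 0.136).

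The next comparison asked whether transcription followed the time since the last earlier fire, with treatment in the model. Photosynthesis KOs, the reaction centres and antenna proteins of cyanobacteria, algae and plants, passed camera alone, in the direction of lower values than other KOs where the last fire lay further back. Of the 20 members 19 had a slope below 0, with a median of −0.18 per SD of time (camera adjusted p = 0.00733, adjusted p = 0.999 with the estimated correlation, fry adjusted p = 0.958). The photosystem II core protein D2 (K02706) had a slope of −0.50 and D1 (K02703) of −0.49, and 0 members passed limma adjusted over the list alone, with 0 at an unadjusted p under 0.05. The list was not called with KOs above 0 in at least 50% of samples alone (adjusted p = 0.115), nor without any of the control samples of gaps 13, 24N and 37 or the fire samples of gaps 24N, 40 and 59.

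Limma called 0 KOs for time since fire, with 25 at an unadjusted p under 0.05 against 63.75 expected by chance, and voom on recovered reads also called 0. The smallest p values belonged to the lysosomal peptidase K01279 (0.81 ± 0.24, adjusted p = 0.940), the response regulator MprA (K07669, 0.95 ± 0.32) and the dipeptidase K05604 (0.51 ± 0.20), and all missed the threshold. Limma called 0 genera, with 26 at an unadjusted p under 0.05, and voom on recovered reads called 16. Coniochaeta, a wood and soil fungus (−1.25 ± 0.36), Mikania, a climbing plant (−1.60 ± 0.48), and Ampulex, a wasp (0.98 ± 0.29), came nearest, each with an adjusted p of 0.223. Time since fire accounted for 4.15% of KO variation (permutation p = 0.1199) and 4.37% of genus variation (permutation p = 0.0848).

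Where more fires had burned in the past, gene-level values tended to be higher in most KOs. Of 1275 KOs 350 had a positive slope at an unadjusted p under 0.05 and 0 a negative slope, and the median slope was 0.47 per SD of past fires. A single KO passed over all KOs, the eukaryotic ribosomal protein L3e (K02925, 1.41 ± 0.31, limma adjusted p = 0.00807), which was above 0 in 10 of 21 control and 3 of 16 fire samples. GroEL (K04077, 1.02 ± 0.26, adjusted p = 0.0708) and the bacterial ribosomal protein L32 (K02911, 1.11 ± 0.30, adjusted p = 0.0794) came next and missed the threshold. The KO total tended to be higher with more past fires over all samples (Pearson r = 0.361, permutation p = 0.0287, Benjamini-Hochberg 0.0475 over 23 relations; Spearman rho = 0.307, permutation p = 0.0655, Benjamini-Hochberg 0.0941), and r was 0.316 without the 2 samples farthest from the median number of fires. Within control samples r was 0.274 (permutation p = 0.231) and within fire samples 0.541 (permutation p = 0.0310; Spearman rho 0.513, permutation p = 0.0449, Benjamini-Hochberg 0.0688). Without the 2 farthest samples r was 0.0166 in control and 0.223 in fire, so the relation within each treatment rested largely on 2 samples. The p values over all samples take each sample as separate, although 9 of the 28 gaps enter with both treatments and the same number of past fires.

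**Figure D4:**
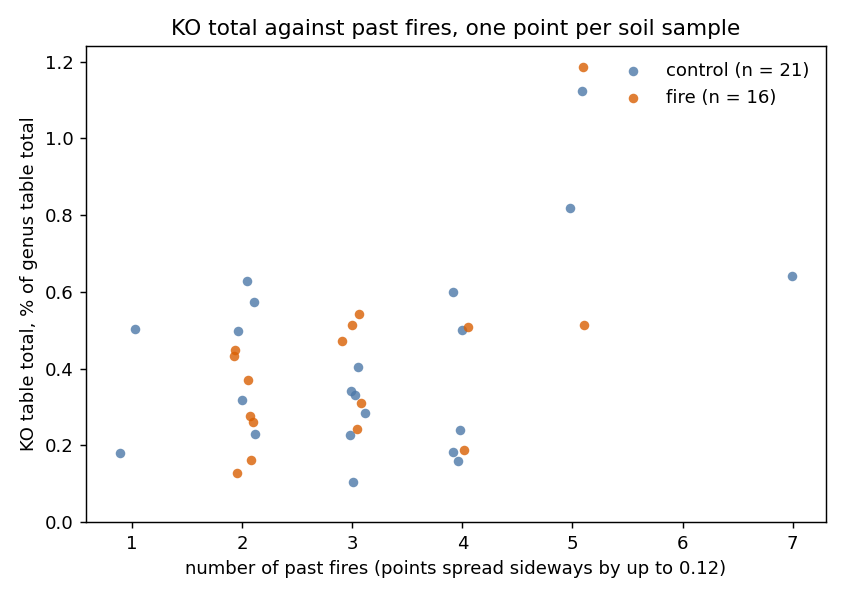
KO table total as a percent of the genus table total against the number of past fires, with a point per soil sample, control samples in blue (n = 21) and fire samples in orange (n = 16). Values run from 0.105% to 1.19% over gaps with 1 to 7 past fires.

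The lists tested for past fires were added after the data had been seen. Of 24 KO lists 5 passed camera. Chaperones had 8 of 8 members with a positive slope (median 0.92, adjusted p = 1.1e-05, adjusted p = 0.568 with the estimated correlation), 7 of them passing adjusted over the list alone, and quality-control proteases had 6 of 6 (median 0.85, 0.0188, 0.840 with the estimated correlation), 4 of them passing adjusted over the list alone. Ribosomal proteins had 63 of 64 (median 0.61, 0.00754, 0.968 with the estimated correlation) with 15 passing adjusted over the list alone, and translation and transcription 10 of 10 (median 0.69, 0.00754, 0.840 with the estimated correlation) with 6. Photosynthesis had camera direction down (8.5e-08, 0.568 with the estimated correlation) although its median slope was 0.05 and fry gave the direction up (fry adjusted p = 0.704). With the same total in every sample the median slope of all KOs was 0.28, with the centred log-ratio 0.02, and with voom on each sample's own total 0.04; limma called 0 KOs in all of these. Leaving out the control sample of gap 37 raised the count of KOs from 1 to 125, and leaving out the control sample of gap 22E or 23 or the fire sample of gap 15 or 19E lowered it to 0.

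Among genera, limma called Sporothrix, a fungus of soil and plant matter, as higher with past fires (2.09 ± 0.45, adjusted p = 0.0190), though it was above 0 in only 5 control samples and 1 fire sample. The plant pathogen Xanthomonas (1.71 ± 0.43, adjusted p = 0.0763) and the bacterium Calditerrivibrio (0.32 ± 0.09, adjusted p = 0.124) missed the threshold. Sporothrix was not called without the control sample of gap 22E (0.217), 23 (0.0707) or 28 (0.0591), and no genus list passed. The rank test called 1 other genus and not Sporothrix (adjusted p = 0.0773), and 8 of 100 reorderings of past fires gave at least 1 genus, so chance cannot be excluded for this call. Past fires accounted for 4.40% of KO variation (permutation p = 0.1) and 3.80% of genus variation (permutation p = 0.140).

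The last comparison asked whether the response to the new fire depended on the earlier fires, which is the question in the series title. Over time since fire, the chaperone list passed camera alone, in the direction of a larger fire response than other KOs where more time had passed. All 8 members had an interaction above 0, with a median of 0.66 per SD (camera adjusted p = 0.00530, adjusted p = 0.967 with the estimated correlation, fry adjusted p = 0.995), with 0 passing limma adjusted over the list alone and 0 at an unadjusted p under 0.05. GroEL had an interaction of 0.80 ± 0.56, and the list was not called with the gap as a fixed block (0.554) or without the fire sample of gap 8 or 93. Among genera, Actinobacteria had 12 of 12 interactions above 0 (median 0.28, adjusted p = 0.0140, 0.252 with the estimated correlation), and Burkholderiales had 3 of 4 below 0 (median −1.05, adjusted p = 0.0302, 0.151 with the estimated correlation). Limma called 0 KOs (20 at an unadjusted p under 0.05) and 0 genera (14), and voom on recovered reads called 0 KOs and 3 genera. The smallest p values, all missing the threshold, belonged to serine dehydratase (K01752, −1.46 ± 0.49), mandelate racemase (K01781, −1.68 ± 0.65) and cathepsin K (K01371, 1.31 ± 0.51), and to Selenomonas (3.67 ± 1.17), Hebeloma (−1.07 ± 0.38) and Flavobacterium (2.13 ± 0.78).

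Over the number of past fires, limma called 2 genera. Phytomonas had an interaction of −3.47 ± 0.70 (adjusted p = 0.00382), with slopes of 0.43 per SD in control and −3.04 in fire soil. The fire slope rests in part on zeros, which stand for values below the floor, and the call was lost with a pseudocount of 36.6. The Korarchaeota row, an archaeal lineage known from hot springs, had an interaction of 2.04 ± 0.39 (adjusted p = 0.00300) and was above 0 in 2 fire samples alone, those of gaps 15 (76.4) and 19E (112), both with 5 past fires. Sulfolobus, a heat-loving archaeon (2.06 ± 0.58), and Pneumocystis, a fungus (−3.24 ± 0.91), each had an adjusted p of 0.126. With the gap as a fixed block limma called 0 genera (15 at an unadjusted p under 0.05), and without the fire sample of gap 15, 19E or 43 it called 5, 12 and 4. Limma called 0 KOs (34 at an unadjusted p under 0.05), as did voom, and bacitracin synthase 3 (K16095, 1.76 ± 0.50, adjusted p = 0.634), the transporter K13868 (1.57 ± 0.54) and phosphoglycerate mutase (K15633, −1.90 ± 0.73) came nearest. In tests added after the data had been seen, photosynthesis (18 of 20 interactions below 0, median −0.39) and eukaryotic markers (9 of 9, median −0.78) passed camera, each with an adjusted p of 0.000249 that became 0.939 with the estimated correlation.

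**Figure D5:**
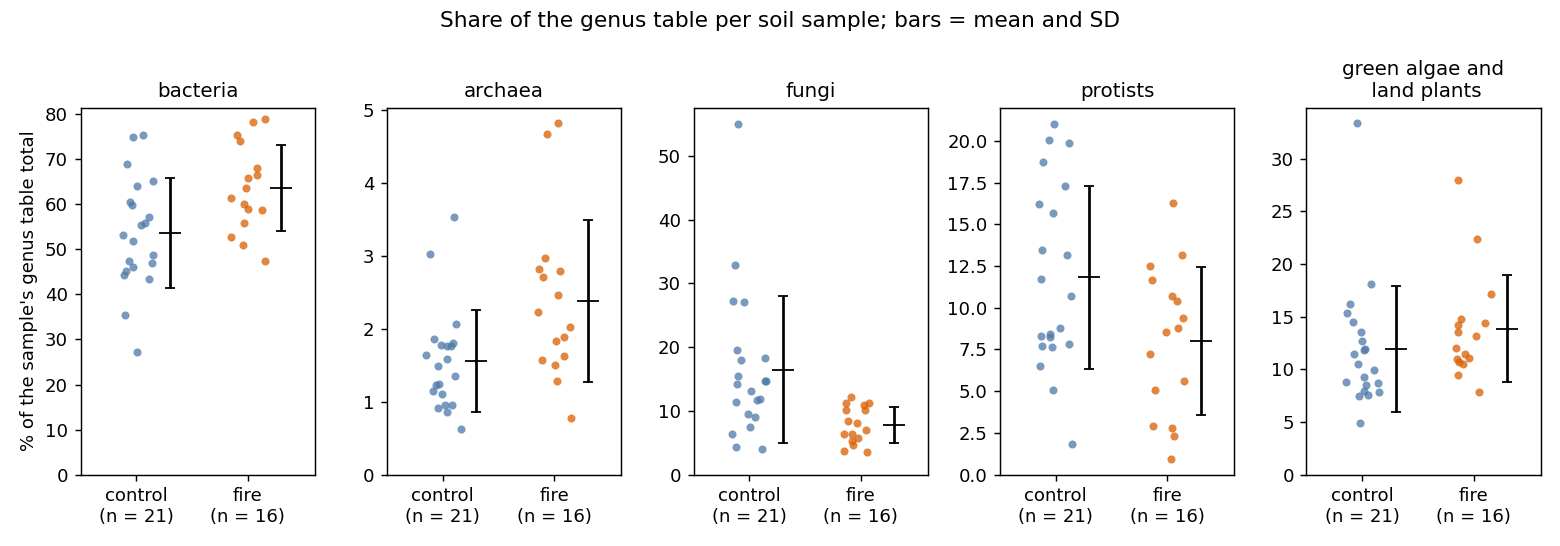
Share of the genus table total taken by bacteria, archaea, fungi, protists and by green algae and land plants in each soil sample, with control samples in blue (n = 21), fire samples in orange (n = 16) and black marks for the mean and SD. Fungi averaged 16.5% in control and 7.79% in fire soil, and bacteria 53.7% and 63.6%.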

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

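The list results by number of past fires in this part come from tests chosen only after the data had been seen, as does the count over reordered samples; the others were planned. The results below were picked out because the response to fire differed with fire history, by the interaction term of the fit. The interaction of fire with past fires was 2.04 for the Korarchaeota row (adjusted p = 0.00300), which was above 0 in 2 fire samples and no control sample. It was −3.47 for Phytomonas (adjusted p = 0.00382), which was above 0 in all 21 control samples and in 12 of 16 fire samples. The fire samples at 0 were those of gaps 15 and 19E (5 past fires each), 24N (4) and 8 (3). The Phytomonas interaction therefore rests in part on values below the floor. With a pseudocount of 36.6 in place of 1, only 1 genus was called, with a positive interaction, so Phytomonas lost its call. When past fires were reordered within treatments, 7 of 100 orders, the real one included, gave at least 2 genera and the highest other gave 3, so chance cannot be excluded for this count.

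For time since fire, the median interaction of the chaperone list was 0.66 (camera adjusted p = 0.00530), that of Actinobacteria 0.28 (0.0140) and that of Burkholderiales −1.05 (0.0302). For past fires, the median interaction was −0.39 for photosynthesis and −0.78 for eukaryotic markers, each with a camera adjusted p of 0.000249. None of these list calls held with the estimated correlation (adjusted p 0.967, 0.252, 0.151, 0.939 and 0.939).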

How the results depend on the processing

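The fits with voom, those without libraries under 1000 KO reads, those without collagen KOs and the list tests for past fires were chosen only after the data had been seen. Of the values of named genes and groups, 38 grew stronger, 32 weaker and 4 turned under the alternatives other than leaving out samples, and 29 grew stronger, 30 weaker and 0 turned on leaving out samples. The direction turned with the gap as a fixed block for K11188 with fire (−0.0634), for K15633 in the interaction with past fires (0.68), for Flavobacterium in the interaction with time since fire (−0.14) and for Sulfolobus in the interaction with past fires (−1.92). The difference in Shannon diversity of KOs turned to −0.0382 in the gaps with both treatments, −0.151 without libraries under 1000 KO reads, −45.6 as the number of KOs above 0 and −0.460 without collagen KOs, and that of genera to 0.0143 in the gaps with both treatments. The fire share of KO profiles was 3.26% on square roots and 4.70% within gaps, and that of genus profiles 6.90% within gaps.

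KOs changed by fire numbered 0 in the main test, 8 with the centred log-ratio, 1 with array weights, 7 with voom on each sample's own total and 1 without the fire sample of gap 94. KOs following past fires (1) numbered 51 with a 10 times larger pseudocount, 4.1e+02 with array weights and 7 with both fire-history measures in 1 model. They numbered 0 with KOs above 0 in at least 50% of samples alone, the same total in every sample, that total without collagen KOs, the centred log-ratio, no trend, the rank test, control samples alone and voom on own totals. Without the fire sample of gap 15 or 19E or the control sample of gap 22E or 23 they numbered 0, without the control sample of gap 9, 31, 46W or 89 or the fire sample of gap 43, 70N or 93 they numbered 2, and without the control sample of gap 37 125.

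Genera changed by fire (7) numbered 0 with the gap as a fixed block, 1 with array weights, 55 with voom and 52 with voom on own totals. They numbered 11 without the control sample of gap 43, 65E or 94, and 13 without the fire sample of gap 97. Genera following time since fire (0) numbered 1 with array weights and without the fire sample of gap 19E, 16 with voom and 23 with voom on own totals. Genera following past fires (1) numbered 0 with genera above 0 in at least 50% of samples alone and with log-scaled past fires, 2 with array weights and with both measures in 1 model, 16 with voom and 13 with voom on own totals. They numbered 0 without the control sample of gap 22E, 23 or 28, 2 without the fire sample of gap 15 or the control sample of gap 20, 35N or 37, and 4 without the fire sample of gap 9 or 19E. Interactions with time since fire (0 genera) numbered 3 with either voom. Interactions with past fires (2 genera) numbered 1 with a pseudocount of 50% of the smallest value above 0 (36.6, larger than the main one of 1), with Phytomonas lost. They numbered 1 with genera above 0 in at least 50% of samples alone and 0 with the fixed block and with array weights. With the centred log-ratio they numbered 14, with voom 8 and with voom on own totals 10. They numbered 5, 12 and 4 without the fire samples of gaps 15, 19E and 43.

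With the estimated correlation 0 lists were called for every term and table. KO lists called for fire (4) numbered 0 with fry and 1 with the fixed block. KO lists for time since fire (1) numbered 0 with fry and with the filter on low KOs, and 2 with the same total without collagen KOs, with log-scaled time and without the fire sample of gap 19E or the control sample of gap 23. They numbered 0 without the control sample of gap 13, 24N or 37 or the fire sample of gap 24N, 40 or 59. KO lists for past fires (5) numbered 16 with fry, 3 with the same total and without the fire sample of gap 15, 2 with the total without collagen KOs and without the control sample of gap 22E, and 6 without the fire sample of gap 19E. Interaction lists of KOs with time since fire (1) numbered 0 with fry, with the fixed block and without the fire sample of gap 8 or 93. Those with past fires (2) numbered 0 with fry, 5 with the filter, and 1 with the fixed block and without the fire sample of gap 19E.

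Genus lists for fire (2) numbered 0 with the same total, and 1 with the filter (host-associated lost) and with fry, the centred log-ratio, the fixed block and fire history as covariates (Actinobacteria lost). They numbered 1 without the control sample of gap 20, 24N or 89 or the fire sample of gap 31, 43, 70N or 93. Genus lists for time since fire (0) numbered 1 with the smaller pseudocount and with log-scaled time, and 2 without the control sample of gap 37. Those for past fires (0) numbered 1 without the control sample of gap 22E. Interaction lists of genera with time since fire (2) numbered 0 with fry, the filter, the centred log-ratio and without the fire sample of gap 13, and 1 with either other pseudocount. They numbered 1 without the control sample of gap 13, 23, 24N, 40 or 46W or the fire sample of gap 15, 24N or 97, and 4 without the fire sample of gap 43 or 93.

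The centred log-ratio moved the median KO difference with fire from −0.15 to −0.03, voom on own totals to −0.33, the omission of libraries under 1000 KO reads to −0.31 and the total without collagen KOs to −0.24. The median KO interaction with time since fire moved from −0.08 to 0.11 with the same total, 0.22 with array weights, 0.23 with voom and 0.39 with voom on own totals. That with past fires moved from 0.06 to −0.09 with the same total, −0.28 with voom on own totals and 0.74 with the fixed block. The median genus interaction with past fires moved from −0.18 to 0.07 with the centred log-ratio, −0.31 with voom and −0.38 with voom on own totals. The fixed block could not be fitted for time since fire or past fires themselves, which are the same within a gap, rank tests were not run for interactions, and count tools were not run on these normalised values.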

Other observations

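The groups of genera, ratios and correlations in this part, and the tests of chaperones, of the eukaryotic groups, of the splits and of the share of KO reads, were chosen only after the results had been seen; the tests of the summed marker share, of the library with 7 past fires and of the neighbours of Virgibacillus were written down before their results. Summed over genera, fungi had a lower mean share in fire soil; the p values of groups below test the log2 sum of normalised values and not the share. Fungi took 7.79 ± 2.87% of the genus total in fire soil (SD, n = 16) and 16.5 ± 11.6% in control soil (n = 21; log2 sum permutation p = 0.00262, Benjamini-Hochberg 0.0134 over 18 tests). Bacteria took 63.6 ± 9.62% and 53.7 ± 12.2% (log2 sum p = 0.00151, adjusted 0.0134), and archaea 2.37 ± 1.11% and 1.55 ± 0.70% (log2 sum p = 0.00298, adjusted 0.0134). Protists took 8.03 ± 4.44% and 11.8 ± 5.50% (log2 sum p = 0.0591, adjusted 0.106), green algae and land plants 13.8 ± 5.06% and 11.9 ± 5.94% (log2 sum p = 0.0720, adjusted 0.118), and animals 4.35 ± 2.39% and 4.55 ± 2.16% (log2 sum p = 0.955). The 2 virus rows were listed at 0 in all control samples and took 0.0285 ± 0.0487% in fire soil (log2 sum p = 0.0101, adjusted 0.0347), but were higher in fire in only 1 of the 9 gaps with both treatments (exact p = 1). All eukaryotes together were lower by 0.33 on the log2 scale (p = 0.0347, adjusted 0.0694). In those 9 gaps fungi were higher in fire in 2 (exact sign-flip p = 0.102), bacteria in 7 (exact p = 0.0938) and archaea in 6 (exact p = 0.281). The row assigned to each group was set by hand from the genus name, and all rows outside the other groups were counted as bacteria.

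Chaperone KOs moved together from sample to sample. DnaK and ClpB had a Pearson r of 0.984 among fire samples (Spearman rho 0.950, permutation p = 1e-05 for both, the smallest these resamples can give, adjusted 2.6e-05 and 4.6e-05 over 23 relations; r = 0.967 without the 2 farthest samples) and 0.899 among control samples (rho 0.792, p = 1e-05 and 5e-05, adjusted 2.6e-05 and 0.000115; r = 0.728 without the 2 farthest). This was not particular to chaperones in fire soil, where DnaK and the elongation factor EF-Tu had an r of 0.794 (rho 0.729, p = 0.00034 and 0.00156, adjusted 0.000782 and 0.00276; r = 0.535 without the 2 farthest); in control soil r was 0.271 (rho 0.200, p = 0.241 and 0.381, adjusted 0.252 and 0.398; r = 0.0745 without the 2 farthest). The 7 fire samples above the highest control value of DnaK were those of gaps 8, 13, 15, 19E, 24N, 70N and 93, with 2 to 33 years since the last fire. Of these gaps only 13 and 24N also had a control sample with values. In gaps 8, 15, 19E, 70N and 93 an effect of fire cannot be told apart from a difference between gaps.

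Higher chaperone transcripts in fire soil are the first pattern weighed. Measured within each sample, DnaK over EF-Tu was 1.32 higher on the log2 scale in fire soil (permutation p = 0.0270, adjusted 0.0694), and the chaperone sum over the ribosomal and translation sum was 0.59 higher (p = 0.141), with a mean of −0.10 over the 9 gaps with both treatments (exact p = 0.766). A like rise of ribosomal proteins is argued against, since chaperones minus ribosomal proteins of the same sample rose by 0.92 ± 0.34 (SE) as member means (permutation p = 0.0076) and by 0.99 ± 0.36 as sums (p = 0.00551), and the ribosomal list had a median of −0.34. Over the 9 gaps these differences averaged 0.38 (exact p = 0.406) and 0.17 (exact p = 0.699). A like rise of translation and transcription KOs cannot be told apart from a rise of chaperones, because the difference was 0.64 ± 0.24 as member means (p = 0.0113) but 0.44 ± 0.44 as sums (p = 0.32). A factor per sample, such as the authors' scaling or the size of the KO table, moves all KOs above 0 of a sample alike. It cancels in the differences of sums, but only in part in those of member means, since KOs at 0 do not move with it. As the whole cause such a factor is argued against by the smallest p over 5 references, 0.038 after Bonferroni. This was the last of 4 forms of the test, and of the earlier ones only the centred log-ratio alone passed, so the evidence is weak. The other 3 references were the rescalings, under which the mean of the 8 members was 0.74 ± 0.50 higher with the same total (permutation p = 0.151), 0.61 ± 0.42 with that total without collagen KOs (p = 0.162) and 0.83 ± 0.41 with the centred log-ratio (p = 0.0361), against 0.72 ± 0.63 before (p = 0.257). Whether chaperones rose or other KOs fell was not tested. Camera compares KOs with each other, so rescaling could hardly change its call (adjusted p 0.000368 to 0.00222), which was lost with the estimated correlation (adjusted p = 0.905) and with the gap as a fixed block (0.790). Of 100 splits of the samples, 6 gave the list a p as small (real −log10 p 3.71, highest other 10.85), so chance cannot be excluded either; of 100 splits that part as many gaps only the real one did (highest other 3.39). A heat shock response in some of the fire trays is a hypothesis that the fire treatment leaves open.

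Lower eukaryotic markers are the second pattern. Too few reads in single KOs is argued against by the summed share of the 9 markers in the KO total. It was lower by 1.48 on the log2 scale (permutation p = 0.00186, adjusted 0.0134), and the share without actin was lower by 1.82 (p = 0.0116). Over the 9 gaps with both treatments the exact sign-flip p was 0.121 with actin. Without actin the exact p was 0.285, and the share was higher in fire in 4 gaps. For this list taken alone chance is argued against by the splits, since 1 of 100, the real one, gave a p as small. The real −log10 p was 8.34 and the highest other 6.92. Of splits that part as many gaps, 2 of 100 did (highest other 8.63). The list had the smallest p of 24 KO lists, and the splits did not count that choice. Its call was lost with the estimated correlation (adjusted p = 0.273) and with fry (adjusted p = 0.217), so chance cannot be excluded. A like loss of RNA from all eukaryotes is argued against, since the genus groups moved apart. Fungi differed by −0.84 ± 0.24 (SE), protists by −0.61 ± 0.33, animals by −0.01 ± 0.23 and plants and algae by 0.34 ± 0.18, and the spread of these 4 differences had a permutation p of 0.00185. The test first written down asked for plants and algae to be higher past the threshold, which they were not (p = 0.0720), but a like loss needs a like fall and not only the lack of a rise. Plants and algae minus fungi of the same sample rose by 1.17 ± 0.31 (p = 0.00093), though over the 9 gaps the exact p was 0.0586, and protists did not part from fungi past the threshold (p = 0.603). Death of fungi and protists by heat is a hypothesis that was not tested further.

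Higher KO values with more past fires are the third pattern. Without the library with 7 past fires 251 KOs had an unadjusted p under 0.05, where 63.75 would be expected by chance. Of 100 reorderings of past fires 1, the real one, gave as many as 350 (highest other 312). A reordering of all samples thus reached more than 251 KOs, and none was run without that library. Whether the pattern stands without it therefore cannot be told. The reorderings moved past fires sample by sample, so the samples of a gap did not keep their shared number. A larger share of KO reads in the library, in place of single genes, cannot be told apart from changes of genes. With the same total in every sample the median slope was still 0.28, but it was 0.04 with voom scaled to each sample's own total. Shallow samples list more KOs at 0, since log2 recovered KO reads and KOs above 0 had an r of 0.752 over all 37 samples (rho 0.752, permutation p = 1e-05 for both, adjusted 2.6e-05 and 4.6e-05; r = 0.701 without the 2 farthest), which the log scale could turn into slopes.

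The fall of Virgibacillus stood beside falls of Trypanosoma, Phytomonas and Geosiphon. A candidate explanation is that reads of eukaryotes were assigned to a row with a bacterial name. Of the 10 rows that correlated most with Virgibacillus, 10 were eukaryotic (Nematostella first, with a correlation of 0.708), while 43.5% of the 301 rows compared were eukaryotic. This fits the hypothesis, and reads were not examined.

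For the remaining counts, 1 of 100 splits, the real one, gave as many as 7 genera (highest other 2; the same with splits that part as many gaps, highest other 1), so chance is argued against for that count. As many as 2 genus lists came from 1 of 100 splits, the real one (highest other 1), but from 7 of 100 splits that part as many gaps (highest other 4). For KOs, 25 of 100 splits gave at least 79 at an unadjusted p under 0.05 (highest other 253), and 7 of 100 gave at least 4 called lists (highest other 7), so chance cannot be excluded for these. When past fires were reordered within treatments, 8 of 100 orders, the real one included, gave at least 1 genus (highest other 3), so chance cannot be excluded for Sporothrix, and 3 of 100 gave at least 1 KO (highest other 1). For genera whose fire response depended on past fires, 7 of 100 orders gave at least 2 (highest other 3), which leaves chance open as well.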
